A study of Arabidopsis thaliana with 25 samples.

How the data were processed

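Dissected cotyledons of wild-type Arabidopsis thaliana seedlings were measured by stranded paired-end RNA-seq on DNB-seq. Per the labels, seedlings had grown for 5 days on Murashige and Skoog medium in darkness or in long days, and dark-grown seedlings were then given 1, 6 or 24 h of continuous light. Tissue was fixed in acetone, cotyledons were dissected, and RNA was extracted with a Qiagen micro RNeasy kit after Drosophila cells had been added. How much tissue and how many fly cells went into each extraction is not given in the sources used here. The deposited values are counts per gene for 25 libraries, 5 in each of 5 groups, with Arabidopsis and Drosophila genes in 1 table. The submitters' processing notes name Salmon 1.9.0, HTSeq, R 4.3.2 and the genome build TAIR10, without saying which step used which. If Salmon made the counts they are estimates rounded to whole numbers. The annotation and any filter applied before deposit are not given in the sources used here.

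The table held 53986 entries, of which 38410 were nuclear Arabidopsis genes, 140 plastid genes, 126 mitochondrial genes and 13771 Drosophila genes. The other 1539 entries carry no gene identifier of either species, held 0.119% to 0.741% of a library's counts and were left out. Among the nuclear entries 1128 join several gene identifiers, and all 37282 entries with 1 identifier matched the reference annotation, from which symbols were taken. Merged entries were tested but not assigned to lists, and 31 of 423 list members also occur in merged entries, so their counts are lower bounds. Each library held 17901840 to 24085995 counts. Intervals and floors given for low counts cover counting error only.

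Libraries were scaled by the sum of their Drosophila counts, rescaled to the geometric mean of the Arabidopsis library sizes, and levels are given as spike-scaled CPM, edgeR's count over library size with these sizes. Genes were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) in 1 fit of all 25 libraries, after filterByExpr with a minimum count of 10 and a minimum total of 15. This left 20615 genes, 20454 nuclear (710 of them merged entries), 107 plastid and 54 mitochondrial. The prior degrees of freedom were 16.3 and the common biological coefficient of variation was 0.565. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no threshold on the fold change. A fold change against a group with no counts is given as at least the value that 3 counts over that group would give. Where the group held 1 to 3 counts, a pooled ratio of counts is given with a 95% interval.

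There were 7 comparisons: 1 h, 6 h and 24 h of light and L, each against dark, and 6 h against 1 h, 24 h against 6 h and L against 24 h. The ratio of nuclear-encoded counts to Drosophila counts was compared as a mean of log2 values by a two-sided exact permutation test over 252 assignments, adjusted over the 7 comparisons. Plastid and mitochondrial counts per Drosophila count and as shares of Arabidopsis counts were tested likewise, adjusted over 20 tests. Gene lists were compared with all other tested genes by limma 3.58.1 camera with its preset correlation, on log2 CPM with a prior count of 2, adjusted over 27 lists. The lists were antenna proteins, photosystem and electron transport subunits, Calvin-Benson cycle, photorespiration, tetrapyrrole synthesis, plastid transcription, photoreceptors, repressors and activators of photomorphogenesis, flavonoid synthesis, circadian clock, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase II, cell cycle and DNA replication, growth genes of shade, auxin and gibberellin, seed lipid mobilisation, seed storage proteins, heat shock proteins, qPCR reference genes, markers of root, shoot meristem, stomata, vasculature and epidermis, and plastid-encoded and mitochondrion-encoded genes. Members were written from general knowledge of these pathways, and members without enough counts were not tested.

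Named genes were chosen by a rule: against dark, the 5 genes with the largest increase and the 5 with the largest decrease among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. To these came up to 4 called members of each list described, those that changed most, and 14 genes reported whatever their values. For the other 3 comparisons the rule took 3 genes in each direction. The groups, comparisons, tests, lists and this rule were fixed before the data were examined, and so were most alternatives. These were TMM scaling over Arabidopsis genes, TMM over Drosophila genes, DESeq2 1.42.0 with Drosophila or median-ratio size factors, no low-count filter, a fit of only the 2 groups compared, the replicate number as a block, a threshold on the fold change, each library left out in turn, other sums for the ratio, camera with an estimated correlation and fry. Added after the data had been seen were each set of replicates alone, a batch term, TMM with a block, TMM with an estimated correlation, the ratio without ribosomal RNA genes, and labels exchanged only within the sets of replicates for the ratio and the organelle reads.

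Whether equal replicate numbers mark pairs is not given in the sources used here. Over 17986 genes with a mean count of at least 20, each library's deviation from its group mean was correlated between groups. The correlation of like-numbered libraries across genes, which are not independent, was 0.51 to 0.72 for 1 h and dark, 0.32 to 0.55 for 6 h and dark, 0.23 to 0.49 for 24 h and dark, 0.37 to 0.61 for 6 h and 1 h and 0.31 to 0.55 for 24 h and 6 h. In these comparisons results with the number as a block are given where they differ. For L it was -0.06 to 0.18 with dark and -0.05 to 0.36 with 24 h, so these comparisons were not treated as paired. The plastid share of counts separated replicates 1 and 2 from replicates 3 to 5 in every group, and these sets were treated as batches. In pairs of replicates the lowest chi-square per degree of freedom was 11.1, so no library repeats another.

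The edgeR fit was tested on simulated data with changes put into 50 genes per fold size in 24 h against dark. It called 4% of 2-fold, 56% of 4-fold, 92% of 8-fold and 98% of 16-fold changes, and 12 of 20415 unchanged genes, and in 6 h against dark, simulated without any change, 0 of 20615. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.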

Results

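Transcripts were counted in cotyledons, the seed leaves, of Arabidopsis thaliana seedlings turning from the pale dark-grown to the green light-grown form (photomorphogenesis). Seedlings had grown for 5 days in darkness or under long days, the latter labelled L. Other dark-grown seedlings then had 1, 6 or 24 h of continuous light. No dark group was kept as long, so light is not separated from age or time of day. L and 24 h also differ in age and day length. Each of 5 groups held 5 libraries, replicates 1 to 5. No separate growth dates are given, so p-values measure the spread between these samples. Drosophila cells were added before RNA extraction as an outside yardstick for the amount of plant RNA. Libraries held 17901840 to 24085995 counts each. Drosophila genes took 2.2% of the counts on average in dark, 1.99% at 1 h, 1.13% at 6 h, 0.610% at 24 h and 0.257% in L. Gene levels are spike-scaled CPM, counts over a library size set by its Drosophila counts. The value after ± is the SD of 5 libraries for a level and the SE for a log2 fold change.

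Replicates 1 and 2 differed from replicates 3 to 5 in all 5 groups. The plastid share of Arabidopsis counts had a median of 2.12% in replicates 1 and 2 and of 7.76% in replicates 3 to 5, a mean log2 difference of 2.02, and the sets were defined by this share. The mitochondrial share differed the other way, by -0.97 (exact permutation p = 0.0005). Both sets of replicates held libraries of every group, and values within each set are given for the ratio, the counts of called genes and the organelle reads.

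The first question was how much plant RNA the cotyledons held per unit of fly RNA. Nuclear-encoded Arabidopsis counts per Drosophila count averaged 51.1 ± 22.3 in dark, 52.6 ± 26.9 at 1 h, 93.7 ± 30.3 at 6 h, 171 ± 60.4 at 24 h and 412 ± 122 in L. The ratio was 3.51-fold higher at 24 h than in dark, a log2 difference of 1.81 ± 0.40 (two-sided exact permutation p = 0.00794, adjusted over 7 comparisons 0.0278). In L it was 8.48-fold higher than in dark, a log2 difference of 3.08 ± 0.40 with the same p. No library of the later group overlapped the dark libraries in either comparison, and 0.00794 is the smallest p that 5 against 5 can give. From 6 h to 24 h the ratio rose 1.84-fold (0.88 ± 0.34, exact permutation p = 0.0238, adjusted 0.0417), in 5 of 5 pairs of like number. From 24 h to L, which were not treated as paired, it rose 2.42-fold (1.28 ± 0.32, exact permutation p = 0.0159, adjusted 0.0370). The 1.91-fold value of 6 h over dark (0.93 ± 0.42) and the 1.85-fold value of 6 h over 1 h (0.89 ± 0.40) did not pass (exact p = 0.0635, adjusted 0.0741). At 1 h the ratio was 1.03-fold that of dark (0.04 ± 0.45, exact p = 0.937).

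These log2 differences were 0.99 at 1 h, 1.82 at 6 h, 2.31 at 24 h and 4.19 in L within replicates 1 and 2, and -0.59, 0.34, 1.48 and 2.35 within replicates 3 to 5. For 6 h over 1 h, 24 h over 6 h and L over 24 h they were 0.83, 0.49 and 1.88 in the former and 0.93, 1.14 and 0.87 in the latter. Neither set can pass alone, since 2 against 2 reaches an exact p of 0.333 and 3 against 3 one of 0.1. With the replicate number as a block the exact sign-flip p cannot fall below 0.0625 (adjusted 0.109), so no comparison passes that way. With labels exchanged only within the sets (exact permutation over 120 assignments, added after the data had been seen) 24 h and L over dark and 24 h over 6 h passed (adjusted p = 0.0389 each), and L over 24 h did not (0.0583). The call of 24 h over 6 h held only without 6 h replicate 4 (1.01) or 24 h replicate 1 (1.05). It was lost without 6 h replicates 1 (0.92), 2 (0.90), 3 (0.63) or 5 (0.94) and without 24 h replicates 2 (0.85), 3 (0.92), 4 (0.70) or 5 (0.88). The call of L over 24 h was lost without 24 h replicate 2 (1.31), 3 (1.23) or 5 (1.27). Without dark replicate 4 (1.1) or 6 h replicate 3 (1.18) 6 h over dark passed, and without 1 h replicate 2 or 6 h replicate 3 (1.14 each) 6 h over 1 h did.

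**Figure D1:**
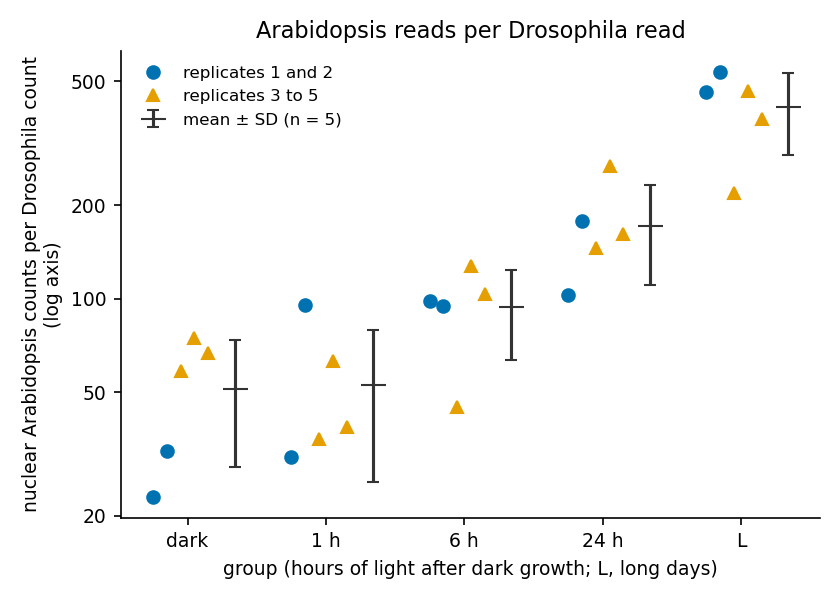
Nuclear-encoded Arabidopsis counts per Drosophila count (log axis) in each of 25 libraries by group, with circles for replicates 1 and 2, triangles for replicates 3 to 5, and bars for the mean ± SD of 5 libraries. Dark libraries lie between 23.1 and 74.7 and L libraries between 219 and 536.

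Gene by gene, most calls after 6 h of light or later were increases when libraries were scaled by their Drosophila counts. The median of 20615 genes tested lay above dark by a log2 fold change of 0.03 at 1 h, 0.56 at 6 h, 1.19 at 24 h and 2.35 in L. TMM scaling, which takes the typical Arabidopsis gene as unchanged, gave values lower by a median of 0.02, 0.56, 1.22 and 2.37 in those comparisons and by 0.54 for 6 h over 1 h, 0.67 for 24 h over 6 h and 1.15 for L over 24 h. Of the genes called against dark, 75.4% were higher at 1 h, 80.9% at 6 h, 93.1% at 24 h and 97.7% in L, against 63.2%, 51.0%, 49.2% and 50.4% under TMM scaling.

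**Figure D2:**
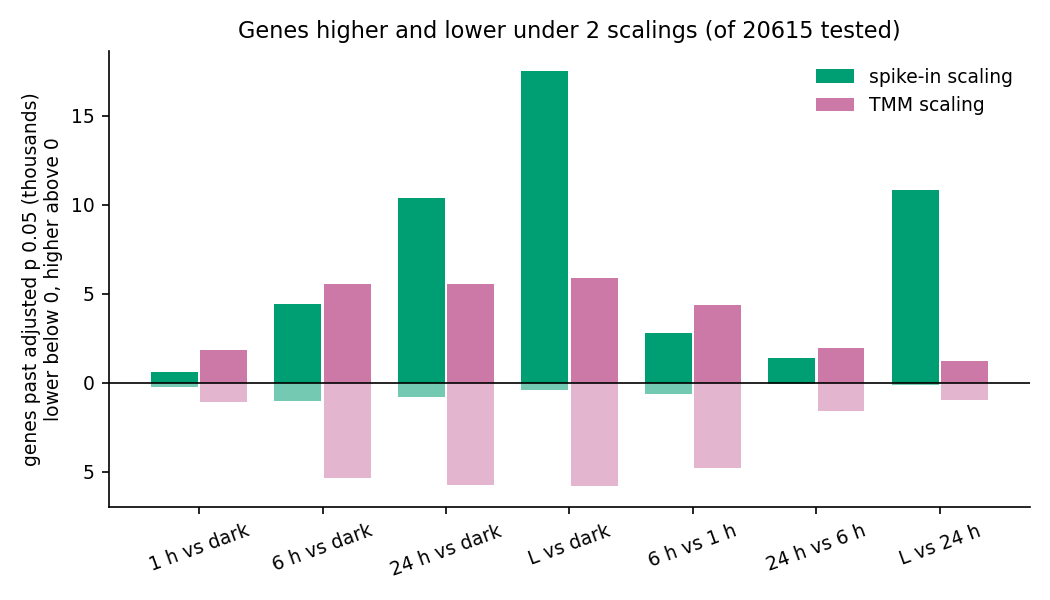
Genes past an adjusted p of 0.05 (in units of 1000 genes, higher above 0 and lower below 0) in 7 comparisons under Drosophila spike-in scaling and under TMM scaling. In L against dark 17495 genes were higher and 404 lower with the spike-in, and 5890 higher and 5796 lower with TMM.

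The comparison of 1 h of light with dark asks which transcripts differ first. Genes of the clock, of light signalling and of light harvesting were among those already higher, while ribosome, cell cycle and seed reserve genes were not called. The test of 20615 genes put 630 higher and 205 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 715 and 331 with the replicate number as a block, where the median turned to -0.04. Leaving out 1 library gave 378 to 690 higher and 130 to 269 lower, with a median from -0.28 to 0.25. Among genes with no counts in dark BBX30 (AT4G15248) reached 12.7 ± 4.80 CPM, at least 937-fold higher. BBX32 (AT3G21150), which like BBX30 codes for a B-box protein, rose from 0.235 ± 0.162 to 104 ± 38.8 CPM, a log2 fold change of 8.85 ± 0.75 (adjusted p = 4.98e-10). AT5G42760 (8.52 ± 0.83), the thionin gene THI2.2 (AT5G36910, 7.35 ± 0.68) and the clock gene PRR9 (AT2G46790, 6.87 ± 0.68) followed. The largest decreases were in the growth-regulating factor gene GRF7 (AT5G53660, -4.87 ± 0.58), the B-box gene bbx23 (AT4G10240, -4.56 ± 0.72), AT4G09530 (-4.56 ± 0.80), AT5G44260 (-4.55 ± 0.72) and AT5G50335 (-4.47 ± 0.77). Their adjusted p ran up to 0.000278.

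Of 17 clock genes 9 rose, 10 adjusted over the list alone and 9 under TMM scaling. They included AT5G64170, also called LNK1 (4.48 ± 0.53), CCA1 (AT2G46830, 3.38 ± 0.64) and ELF4 (AT2G40080, 3.24 ± 0.63). Of 15 repressors of photomorphogenesis 7 rose, against 8 rising and 1 falling adjusted over the list alone (TMM 8 and 2). STH (AT2G31380), also called BBX25, rose by 5.84 ± 0.63, and the COP1 partner genes SPA1 (AT2G46340, 3.09 ± 0.53), SPA3 (AT3G15354, 2.99 ± 0.55) and SPA4 (AT1G53090, 2.98 ± 0.54) rose as well. Of 12 activators 2 rose and 5 fell, 3 and 5 adjusted over the list alone (TMM 2 and 5). The bZIP factor genes HYH (AT3G17609, 2.73 ± 0.57) and HY5 (AT5G11260, 1.96 ± 0.50, adjusted p = 0.016) rose, and bbx23, FHY1 (AT2G37678, -2.33 ± 0.52) and GATA2 (AT2G45050, -2.31 ± 0.43) fell. The HY5 call was lost without dark replicate 1 (1.78) or 1 h replicate 2 (1.47). Of 21 shade, auxin and gibberellin growth genes 4 rose and 4 fell, 6 and 6 adjusted over the list alone (TMM 6 and 5). Among them AT4G38840, also called SAUR14 (4.38 ± 0.66), rose, and HB-2 (AT4G16780), also called ATHB2 (-3.05 ± 0.48), and PIL1 (AT2G46970, -2.74 ± 0.55) fell.

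Of 20 antenna protein genes 5 rose, 8 adjusted over the list alone (TMM 9). CAB2 (AT1G29920), also called LHCB1.1, went from 15.3 ± 15.6 to 266 ± 190 CPM (4.12 ± 0.71), and LHCB2.1 (AT2G05100, 3.61 ± 0.59) and LHCB2.2 (AT2G05070, 3.47 ± 0.62) rose with it. CAB2 shares reads with near-identical genes that the table also counts in merged entries, so its level is uncertain. The same may hold for CAB1, another gene of the LHCB1 group. The early light-induced genes ELIP1 (AT3G22840, 4.51 ± 0.82) and ELIP2 (AT4G14690, 3.83 ± 0.71), which protect from excess light, rose. Of 15 flavonoid genes 4 rose, 10 adjusted over the list alone (TMM 7), among them UGT78D2 (AT5G17050, 4.22 ± 0.68) and F3H (AT3G51240, 3.77 ± 0.86). Of 21 plastid transcription genes 2 rose, over all genes and adjusted over the list alone (TMM 4): SIGE (AT5G24120), the sigma factor gene also called SIG5 (6.50 ± 0.59), and GLK2 (AT5G44190, 3.13 ± 0.53). Calvin-Benson genes gave 2 of 20 and tetrapyrrole genes 3 of 25, with the same counts adjusted over the list alone (TMM 4 and 5). Of 11 heat shock genes 2 rose, 4 adjusted over the list alone (TMM 3): HSFA2 (AT2G26150, 2.75 ± 0.72) and HSP70 (AT3G12580, 2.63 ± 0.74). The HSFA2 call was lost without dark replicate 1 (2.58), 2 (2.59) or 3 (2.66) or 1 h replicate 2 (2.37). The HSP70 call was lost without dark replicate 1 (2.41), 2 (2.50), 3 (2.60) or 5 (2.75) or 1 h replicate 2 (2.41) or 4 (2.47).

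No gene passed among 30 photosystem and electron transport subunits, 14 photorespiration genes, 13 photoreceptors, 41 cytosolic ribosomal proteins, 23 ribosome biogenesis genes, 13 RNA polymerase II subunits, 27 cell cycle genes, 16 seed lipid mobilisation genes, 2 seed storage genes or 11 qPCR reference genes. The same held for 2 root, 7 shoot meristem, 10 stomatal, 7 vascular and 5 epidermal markers and for 107 plastid-encoded and 54 mitochondrion-encoded genes. At an unadjusted p under 0.05 edgeR had 4 photorespiration genes higher, and in each other list at most 1 higher and 1 lower. Adjusted over the list alone 1 root marker rose. Under TMM scaling edgeR called 8 photosystem and 6 photorespiration genes higher, and 4 photoreceptors higher and 2 lower, with at most 2 calls in any other of these lists. The levels of CAB1 (AT1G29930, -0.15 ± 0.50), the Rubisco subunit gene RBCS1A (AT1G67090, -0.03 ± 0.49), the actin gene ACT2 (AT3G18780, 0.10 ± 0.47) and NRPB1 (AT4G35800) for the largest RNA polymerase II subunit (-0.24 ± 0.51) had an adjusted p of 1. The phytochrome gene PHYA (AT1G09570) went from 188 ± 75.7 to 111 ± 47.2 CPM (adjusted p = 0.644) and PORA (AT5G54190), for a protochlorophyllide reductase, from 1051 ± 775 to 370 ± 215 (0.429). ICL (AT3G21720), for isocitrate lyase, had a log2 value of -0.62 ± 0.61. The chalcone synthase gene TT4 (AT5G13930) had 60.8 ± 72.9 and 100 ± 120 CPM, and its value of 0.73 became -0.32 without 1 h replicate 4. The ubiquitin gene UBQ10 (AT4G05320, 1.3 ± 0.43, adjusted p = 0.0945) passed with the replicate number as a block (0.045).

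Against all other genes limma camera called 9 lists at 1 h. Higher were clock (adjusted p = 1.18e-16), antenna (1.92e-10), repressor (2.37e-08), flavonoid (2.99e-08), photorespiration (0.00162), photosystem (0.00411), plastid transcription (0.0153) and heat shock genes (0.0153), and lower were activators (0.00847). None held with an estimated correlation, where the adjusted p was 0.124 for the clock, 0.595 for antenna, repressor and flavonoid genes and 0.971 for the others. With TMM scaling and that correlation the clock (0.00515) and the repressors (0.0259) passed. Plastid-encoded genes passed with the block alone (0.00281, against 0.226). Median, mean and test differed in sign for photoreceptors, cell cycle genes and meristem markers, none of them called. Replicates 1 and 2 alone gave 1745 genes higher and 58 lower, replicates 3 to 5 gave 242 and 345, and TMM scaling of all gave 1843 and 1074. CAB1, RBCS1A, ICL, ACT2 and NRPB1 lay between 0.99 and 1.47 in the former set and between -1.04 and -0.52 in the latter.

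After 6 h of light most genes of photosynthesis, of flavonoids, of cell division and of the stomatal list were higher than in dark, with a part of the translation genes. Some of the genes for using up seed lipid were lower. Of 20615 genes 4413 were higher and 1041 lower, against 5814 and 1542 with the block. DFR (AT5G42800), for dihydroflavonol reductase, had no counts in dark and 15.9 ± 9.10 CPM at 6 h, at least 1228-fold higher. scpl10 (AT2G23000), a serine carboxypeptidase-like gene, rose by 10.32 ± 0.92 on 5 dark counts, all in replicate 2, so the size of this value rests on that library. AT2G32550 had 1293 times its dark level in pooled counts (95% interval 442 to 6274) and AT2G15020 had 1235 times its own (341 to 10210). AT4G16880 rose by 9.59 ± 0.86. PORA fell from 1051 ± 775 to 7.44 ± 5.12 CPM, 142-fold (-7.14 ± 0.94, adjusted p = 5.15e-07). The other large decreases were in bbx23 (-9.22 ± 0.91), GRF7 (-7.98 ± 0.68), AT2G34020 (-7.26 ± 0.67) and FLP1 (AT4G31380, -6.87 ± 0.70).

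Of 20 antenna genes 18 rose, 19 adjusted over the list alone (TMM 18), with CAB2 up to 3261 ± 1791 CPM (7.74 ± 0.84) and LHCB2.2 by 5.62 ± 0.69. Photosystem and electron transport subunits rose in 28 of 30 cases, 30 adjusted over the list alone (TMM 29), PSBO2 (AT3G50820) by 3.65 ± 0.61 and PSAH2 (AT1G52230) by 3.24 ± 0.63. The Calvin-Benson list gave 14 of 20, 16 adjusted over the list alone (TMM 16), with CP12-2 (AT3G62410, 5.70 ± 0.66) and RBCS1B (AT5G38430, 5.12 ± 0.71), the latter also present in merged entries. Photorespiration gave 13 of 14, 14 adjusted over the list alone (TMM 14), with the glycine decarboxylase gene GLDP1 (AT4G33010, 3.42 ± 0.67) and the glycolate oxidase gene GOX1 (AT3G14420, 2.92 ± 0.52). In tetrapyrrole synthesis 13 of 25 rose and 2 fell, 14 and 2 adjusted over the list alone (TMM 17 and 3). GUN5 (AT5G13630), for the H subunit of magnesium chelatase (3.02 ± 0.57), and GUN4 (AT3G59400, 2.64 ± 0.51) rose, and PORA fell. Plastid transcription gave 9 of 21, 13 adjusted over the list alone (TMM 14). All 15 flavonoid genes rose over all genes, adjusted over the list alone and under TMM, with LDOX (AT4G22880) by 9.25 ± 0.96, F3H by 4.42 ± 0.89 and TT4 to 490 ± 262 CPM (3.01 ± 0.90, adjusted p = 0.012). ELIP1 reached 3619 ± 1567 CPM (6.99 ± 0.92) and ELIP2 rose by 5.31 ± 0.76.

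Cytosolic ribosomal proteins gave 16 of 41, 20 adjusted over the list alone (TMM 25 higher, 1 lower), among them AT5G03850, also called RPS28C (2.14 ± 0.56), and RPS6 (AT4G31700, 1.99 ± 0.58). Ribosome biogenesis gave 12 of 23, 14 adjusted over the list alone (TMM 14 and 1), with NOP56 (AT1G56110, 2.15 ± 0.57). Cell cycle and DNA replication gave 17 of 27, 22 adjusted over the list alone (TMM 21). There RNR2A (AT3G23580), for ribonucleotide reductase, rose by 2.85 ± 0.58, the sliding clamp gene PCNA1 (AT1G07370) by 2.73 ± 0.63 and MCM3 (AT5G46280) by 2.18 ± 0.61. In the stomatal list 6 of 10 rose, 6 adjusted over the list alone (TMM 7 higher, 1 lower): among them EPF2 (AT1G34245, 3.11 ± 0.51) and the lineage regulators MUTE (AT3G06120, 2.55 ± 0.51) and SPCH (AT5G53210, 2.12 ± 0.55). Growth genes gave 13 higher and 4 lower of 21, the same adjusted over the list alone (TMM 12 and 6), with AT4G38860, also called SAUR16 (6.80 ± 0.70), the expansin gene EXPA1 (AT1G69530, 5.49 ± 0.64) and PIL1 (-4.12 ± 0.60). Repressors gave 9 higher and 1 lower of 15, 10 and 1 adjusted over the list alone (TMM 10 and 3), with STH (5.69 ± 0.63) and PIF7 (AT5G61270, 5.64 ± 0.52). Activators gave 2 higher and 6 lower of 12, 2 and 7 adjusted over the list alone (TMM 2 and 8), with LZF1 (AT1G78600), also called BBX22 (4.2 ± 0.70), and FHY1 (-3.29 ± 0.54).

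Of 16 seed lipid genes 6 fell, 8 adjusted over the list alone, while TMM put 15 lower and 1 higher. ICL went from 936 ± 725 to 60.7 ± 37.2 CPM (-3.95 ± 0.68), and PCK1 (AT4G37870), for phosphoenolpyruvate carboxykinase, fell by 3.99 in log2. The malate synthase gene MLS (AT5G03860) fell too (-2.19 ± 0.69), a call lost without dark replicate 4 (-1.69). Clock genes gave 8 higher and 1 lower of 17, the same adjusted over the list alone (TMM 5 and 4). Of 13 photoreceptors PHYA fell (-2.53 ± 0.46) and PHYB (AT2G18790) rose (1.52 ± 0.49, adjusted p = 0.0205), the same adjusted over the list alone (TMM 3 higher, 5 lower). The PHYB call was lost without dark replicate 1 (1.3) or 2 (1.34) or 6 h replicate 4 (1.33) or 5 (1.39). RNA polymerase II subunits gave 3 of 13, 7 adjusted over the list alone (TMM 4 higher, 2 lower), epidermal markers 2 of 5 and 4 (TMM 4) and heat shock genes 2 of 11 and 2 (TMM 1). Reference genes gave 1 of 11, 0 adjusted over the list alone (TMM 3 higher, 3 lower), meristem markers 1 of 7 and 0 (TMM 1 and 2), and plastid-encoded genes 13 of 107 and 8 (TMM 7). No seed storage gene, root marker, vascular marker or mitochondrion-encoded gene passed, where edgeR had 2 vascular and 3 mitochondrial genes higher at an unadjusted p under 0.05 and TMM scaling called 2 mitochondrial genes lower. RBCS1A (1.18 ± 0.50, adjusted p = 0.0736) and ACT2 (1.21 ± 0.48, 0.0577) passed with the block (0.00914 and 0.0242), without dark replicate 4 (1.42 and 1.37) and without 6 h replicate 3 (1.33 and 1.36). CAB1 (0.79 ± 0.51), CCA1 (-0.10 ± 0.58) and NRPB1 (-0.30 ± 0.51) did not pass, nor did HY5 (0.26 ± 0.49, under TMM -0.37) or UBQ10 (0.53 ± 0.43, under TMM -0.08).

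By camera 14 lists differed from the other genes at 6 h. Photosystem (adjusted p = 9.83e-13), antenna (4.78e-13), flavonoid (3.20e-09), Calvin-Benson (3.58e-07), photorespiration (5.73e-07), cell cycle (0.000113), repressor (0.00201), cytosolic ribosomal (0.00201), ribosome biogenesis (0.00228), plastid transcription (0.00228), tetrapyrrole (0.0158) and stomatal genes (0.0176) were higher. Seed lipid genes (5.36e-07) and activators (0.000192) were lower. An estimated correlation gave an adjusted p of 0.595 for photosystem, antenna, flavonoid, photorespiration, seed lipid and activator genes. It was 0.649 for the Calvin-Benson cycle and 0.881 for the rest. The tetrapyrrole call was lost in replicates 3 to 5 (0.0652). Reference, plastid-encoded and mitochondrion-encoded genes, none called, had a median, mean and test of differing sign. Within replicates 1 and 2 there were 8463 genes higher and 246 lower, within replicates 3 to 5 1737 and 1140, and under TMM scaling 5551 and 5338.

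With the spike-in all the lists of photosynthesis were higher after 24 h of light almost to the last gene. So were most genes of translation and cell division, and TMM called fewer of these higher. Of 20615 genes 10377 were higher than in dark and 775 lower, and 12170 and 952 with the block. DFR was at least 4969-fold higher, a limit that rests largely on 24 h replicate 5 (188 CPM, the others 6.49 to 46.6), the plastid phosphate translocator gene PPT2 (AT3G01550) at least 2553-fold, AT3G46650 at least 1903-fold and BBX30 at least 1696-fold, all with no counts in dark. AT2G15020 had 8721 times its dark level in pooled counts (95% interval 2413 to 72030). bbx23 went from 93.3 ± 49.9 CPM to no counts, at least 1770-fold lower, and U1.8 (AT5G04455), a U1 small nuclear RNA gene, from 10.8 ± 14.8 CPM to none, at least 322-fold lower, a limit that rests largely on dark replicate 2 (36.7 CPM, the others 0.953 to 9.81). PORA fell to 0.851 ± 0.262 CPM (-10.29 ± 1.08, adjusted p = 2.32e-09) and GRF7 by 9.45 in log2. CYP96A5 (AT2G21910), a cytochrome P450 gene, was lower by a pooled ratio of 563 (95% interval 156 to 4653).

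All 20 antenna genes rose, also adjusted over the list alone (TMM 19). CAB2 reached 13860 ± 4876 CPM (9.83 ± 0.92), LHCB4.3 (AT2G40100) rose by 7.07 ± 0.75 and CAB1 went from 6722 ± 4186 to 27580 ± 10170 CPM (2.04 ± 0.52, adjusted p = 0.00177; under TMM 0.79, 0.0969). All 30 photosystem subunits rose (30 adjusted over the list alone, TMM 30), PSBO2 by 4.96 ± 0.65 and PSAN (AT5G64040) by 4.33 ± 0.56. Calvin-Benson genes gave 18 of 20, 20 adjusted over the list alone (TMM 18), with the Rubisco activase gene RCA (AT2G39730, 5.20 ± 0.63), the aldolase gene FBA1 (AT2G21330, 5.06 ± 0.62) and RBCS1A (2.90 ± 0.53). All 14 photorespiration genes rose by every count, GLDP2 (AT2G26080) by 4.99 ± 0.64 and the serine hydroxymethyltransferase gene SHM1 (AT4G37930) by 4.77 ± 0.61. Tetrapyrrole genes gave 22 higher and 2 lower of 25, the same adjusted over the list alone (TMM 21 and 3), with GUN5 (4.31 ± 0.60) against PORB (AT4G27440, -4.27 ± 0.73) and PORA. Plastid transcription gave 18 of 21, 19 adjusted over the list alone (TMM 12), with SIGE (6.15 ± 0.58). Flavonoid genes gave 13 of 15 by every count, with TT4 at 548 ± 386 CPM (3.17 ± 0.91). ELIP1 was higher by 5.91 ± 0.88 and ELIP2 by 4.48 ± 0.73.

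Cytosolic ribosomal proteins gave 36 of 41, 39 adjusted over the list alone (TMM 24 higher, 1 lower), RPS6 with 2.61 ± 0.59. Ribosome biogenesis gave 18 of 23 and 20 adjusted over the list alone (TMM 9 and 1), and RNA polymerase II 9 of 13 and 10 (TMM 1 and 1), though not NRPB1 (0.63 ± 0.51, under TMM -0.50). Cell cycle genes gave 24 of 27, 24 adjusted over the list alone (TMM 13 and 1), with the Aurora kinase gene AUR1 (AT4G32830, 3.30 ± 0.59) and the cyclin gene CYCA1;1 (AT1G44110, 2.94 ± 0.63). Stomatal markers gave 7 of 10 and 7 adjusted over the list alone (TMM 7 higher, 3 lower), with MUTE (3.22 ± 0.52) and EPF1 (AT2G20875, 3.06 ± 0.49). Vascular markers gave 5 of 7 and 5 (TMM 2), with SEOR1 (AT3G01680) of the phloem (2.98 ± 0.47), and epidermal markers 4 of 5 and 4 (TMM 2), with the lipid transfer gene LP1 (AT2G38540, 3.64 ± 0.71). Photoreceptors gave 5 higher and 2 lower of 13, the same adjusted over the list alone (TMM 3 and 5), PHYE (AT4G18130) with 2.62 ± 0.50, PHYB with 2.31 ± 0.51 and PHYA with -2.56 ± 0.46. Repressors gave 12 of 15, 12 adjusted over the list alone (TMM 10 higher, 2 lower), with PIF7 (7.04 ± 0.55) and SPA4 (4.18 ± 0.57). Activators gave 2 higher and 7 lower of 12, 3 and 7 adjusted over the list alone (TMM 1 and 9), with HYH (3.76 ± 0.60) and FHY1 (-3.14 ± 0.53). HY5 did not pass (-0.15 ± 0.49), but did under TMM (-1.50, adjusted p = 0.00264).

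Seed lipid genes gave 1 higher and 4 lower of 16, the same adjusted over the list alone, against 1 and 15 under TMM. The malate dehydrogenase gene PMDH2 (AT5G09660) rose (2.84 ± 0.51), and ICL (-6.35 ± 0.77), PCK1 (-4.91 ± 0.60) and MLS (-3.81 ± 0.74) fell. Clock genes gave 8 higher and 3 lower of 17, the same adjusted over the list alone (TMM 7 and 8), with LHY (AT1G01060, 4.80 ± 0.85) and CCA1 (4.66 ± 0.68). Growth genes gave 10 higher and 4 lower of 21, the same adjusted over the list alone (TMM 9 and 7), with EXPA1 (5.91 ± 0.65) and PIL1 (-3.21 ± 0.57). Heat shock genes gave 4 higher and 1 lower of 11, the same adjusted over the list alone, though TMM called 0 higher and 2 lower, with ATHSP22.0 (AT4G10250) lower (-2.59 ± 0.61). Reference genes gave 6 of 11, 7 adjusted over the list alone, though TMM called 3 higher and 3 lower, among them GAPC1 (AT3G04120, 2.03 ± 0.54), YLS8 (AT5G08290, 1.79 ± 0.46) and UBQ10 (1.73 ± 0.44). ACT2 had 1.62 ± 0.49, and UBQ10 and ACT2 did not pass under TMM (0.34 each). Of 7 meristem markers 2 fell, 1 adjusted over the list alone (TMM 4), namely STM (AT1G62360, -2.16 ± 0.57) and KNAT2 (AT1G70510, -1.47 ± 0.62, adjusted p = 0.0435). The KNAT2 call was lost without dark replicate 4 (-1.12) or 5 (-1.28) or 24 h replicate 1 (-1.36), 3 (-1.38), 4 (-1.58) or 5 (-1.42). Plastid-encoded genes gave 38 of 107, 31 adjusted over the list alone (TMM 5 higher, 1 lower), and mitochondrion-encoded genes 10 of 54 and 2, though TMM called 3 lower. No seed storage gene or root marker passed, also at an unadjusted p under 0.05 in edgeR, and TMM called 1 seed storage gene lower.

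Camera called 16 lists at 24 h. Higher were antenna (adjusted p = 5.65e-12), photosystem (7.23e-12), Calvin-Benson (3.90e-08), photorespiration (5.56e-08), flavonoid (0.000325), repressor (0.00186), cytosolic ribosomal (0.00475), plastid transcription (0.0163), cell cycle (0.0179), tetrapyrrole (0.0253) and stomatal genes (0.0498). Lower were activators (3.90e-08), seed lipid (2.13e-06), meristem (0.00271), heat shock (0.0453) and mitochondrion-encoded genes (0.0453). With an estimated correlation the adjusted p was 0.560 for antenna, photosystem, Calvin-Benson, photorespiration, activator, seed lipid and meristem genes. It was 0.641 for flavonoids, 0.763 for repressors and 0.817 for the rest. TMM with that correlation left activators and photorespiration (0.0352 each). With the block stomatal (0.0594) and mitochondrion-encoded genes (0.144) lost their calls, and under TMM heat shock (0.578) and mitochondrion-encoded genes (0.658) did. Within replicates 1 and 2 stomatal and mitochondrion-encoded genes did not pass (0.112 each), and within replicates 3 to 5 stomatal (0.0677), mitochondrion-encoded (0.362) and heat shock genes (0.333) did not. Heat shock genes had a median 0.45 above that of all genes and a mean 0.39 below, and median and mean also differed in sign from each other or the test for growth, reference, plastid-encoded and mitochondrion-encoded genes. There were 12861 genes higher and 400 lower in replicates 1 and 2, 5768 and 704 in replicates 3 to 5, and 5557 and 5735 under TMM scaling of all.

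In L, cotyledons held more of nearly every transcript per fly count than in dark. Of 20615 genes 17495 were higher and 404 lower. Under TMM scaling 3278 genes that were higher with the spike-in were called lower. PPT2 was at least 18100-fold higher, the protein kinase gene CIPK20 (AT5G45820) at least 7208-fold and the microRNA gene MIR157c (AT3G18217) at least 4159-fold, all with no counts in dark. In pooled counts AT2G15020 had 29500 times its dark level (95% interval 8165 to 243700) and SQP1 (AT5G24150) had 18100 times its own (6190 to 87780). The largest decreases were in CYP96A5, by a pooled ratio of 160 (54.9 to 778), bbx23 (-7.26 ± 0.86), AT4G35720 (-6.99 ± 0.67), the bHLH gene HEC2 (AT3G50330, -6.70 ± 0.73) and the cysteine protease gene CP1 (AT4G36880, -6.64 ± 0.78). CYP96A5 had counts in L only in replicate 3, on which the size of its ratio rests.

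All antenna, photosystem, Calvin-Benson and photorespiration genes rose, 20, 30, 20 and 14 in number, also adjusted over the list alone (TMM 19, 29, 19 and 14). CAB2 reached 26820 ± 8527 CPM (10.78 ± 0.95) and LHCB2.2 rose by 8.79 ± 0.79, PSBO2 by 6.52 ± 0.70, FBA1 by 6.85 ± 0.68 and RCA by 6.63 ± 0.67. GLDP2 rose by 6.58 ± 0.69 and SHM1 by 6.05 ± 0.65. RBCS1A went from 8126 ± 4707 to 164900 ± 43070 CPM (4.34 ± 0.56, adjusted p = 4.45e-08), and CAB1 rose by 3.06 ± 0.55, without passing under TMM (0.68). Tetrapyrrole genes gave 23 higher and 2 lower of 25, the same adjusted over the list alone (TMM 14 and 2). CH1 (AT1G44446), for chlorophyllide a oxygenase (5.35 ± 0.59), and GUN5 (5.27 ± 0.63) rose, and PORA fell (-6.53 ± 0.91, and -7.88 without L replicate 4, which had 39.6 CPM against 0.808 to 11.8 in the others). Plastid transcription gave 19 of 21, 19 adjusted over the list alone, though TMM called 7 higher and 6 lower, with SIGE (7.80 ± 0.63) and GPRI1 (AT2G20570), also called GLK1 (5.07 ± 0.65). Flavonoid genes gave 14 of 15, 14 adjusted over the list alone (TMM 13 higher, 1 lower), with 4CL3 (AT1G65060, 7.04 ± 1.11), F3H (7.03 ± 1.01) and TT4 (4.71 ± 0.97). ELIP1 (6.51 ± 0.91) and ELIP2 (6.34 ± 0.80) rose too.

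Every cytosolic ribosomal (41), ribosome biogenesis (23), RNA polymerase II (13) and cell cycle gene (27) rose, also adjusted over the list alone. Under TMM 12, 13, 1 and 12 were higher, and 2 RNA polymerase II genes were lower. AT5G08180, also called NHP2 (5.25 ± 0.82), NOP56 (3.61 ± 0.61), NRPB12 (AT5G41010, 3.20 ± 0.68), NRPB4 (AT5G09920, 2.92 ± 0.49) and RNR2A (5.22 ± 0.65) were among those that rose most. NRPB1 rose from 17.0 ± 11.3 to 66.7 ± 19.2 CPM (1.98 ± 0.53, adjusted p = 0.00101), but had -0.24 under TMM (adjusted p = 0.459). All 11 reference genes rose, also adjusted over the list alone (TMM 3 higher, 2 lower): YLS8 and GAPC1 by 3.23, ACT2 by 3.16 ± 0.51 and UBQ10 by 2.92 ± 0.46. All 10 stomatal and all 7 vascular markers rose by both counts (TMM 5 higher and 1 lower, and 4 higher), HT1 (AT1G62400) by 5.34 ± 0.50, FMA (AT3G24140) by 3.93 ± 0.47, SEOR1 by 3.97 ± 0.49 and XCP1 (AT4G35350) by 3.14 ± 0.70. Epidermal markers gave 4 of 5 and 4 adjusted over the list alone (TMM 1 and 1), with LP1 (4.74 ± 0.75). Photoreceptors gave 11 higher and 1 lower of 13, the same adjusted over the list alone (TMM 5 and 4), with PHYE (4.1 ± 0.54), PHOT2 (AT5G58140, 3.74 ± 0.59) and PHYA (-1.63 ± 0.44). Repressors gave 14 of 15, 14 adjusted over the list alone (TMM 11 higher, 2 lower), with PIF7 (9.14 ± 0.60) and PIF4 (AT2G43010, 5.14 ± 0.59).

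Activators gave 4 higher and 6 lower of 12, the same adjusted over the list alone (TMM 2 and 8), with HYH (4.57 ± 0.62) and BZS1 (AT4G39070), also called BBX20 (-3.08 ± 0.47). HY5 had 0.65 ± 0.49 (adjusted p = 0.209), but fell under TMM (-1.98, adjusted p = 0.000200). Growth genes gave 14 higher and 2 lower of 21, the same adjusted over the list alone (TMM 9 and 6), with EXPA5 (AT3G29030, 8.59 ± 0.84) and PIL1 (-3.92 ± 0.62). Clock genes gave 11 higher and 3 lower of 17, the same adjusted over the list alone (TMM 8 and 6), with PRR9 (7.05 ± 0.69) and CCA1 (5.93 ± 0.72). Seed lipid genes gave 8 higher and 3 lower of 16, the same adjusted over the list alone, but 1 and 15 under TMM. PMDH2 rose (4.80 ± 0.56), and ICL (-5.60 ± 0.74) and PCK1 (-2.05 ± 0.53) fell. Heat shock genes gave 9 higher and 1 lower of 11, the same adjusted over the list alone (TMM 6 and 2). HSP17.6II (AT5G12020) rose (7.09 ± 1.07), and ATHSP22.0 was lower by a pooled ratio of 60.3 (95% interval 20.6 to 292). Of 7 meristem markers 2 fell, 2 adjusted over the list alone (TMM 6), STM (-1.87 ± 0.58) and CLV3 (AT2G27250), which had no counts in L and was at least 5.09-fold lower. Of 2 seed storage genes 1 rose, 0 adjusted over the list alone, though TMM called 1 lower, and of 2 root markers 1 rose, 2 adjusted over the list alone (TMM 1). Plastid-encoded genes gave 59 of 107, 56 adjusted over the list alone (TMM 3 higher, 1 lower), and mitochondrion-encoded genes 36 of 54 and 34, though TMM called 7 lower.

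Against the other genes camera called 12 lists in L. Antenna and photosystem (adjusted p = 4.49e-09 each), Calvin-Benson (5.70e-07), photorespiration (1.99e-06), repressor (0.00849) and flavonoid genes (0.0179) were higher. Activators (6.67e-10), meristem (2.71e-08), plastid-encoded (4.13e-06), mitochondrion-encoded (6.91e-06), seed lipid (9.27e-06) and heat shock genes (0.0168) were lower. Estimating the correlation left none, with an adjusted p of 0.157 for activators and meristem markers, 0.737 for heat shock, 0.823 for repressors and flavonoids and 0.513 for the rest. Under TMM with that correlation activators and photorespiration passed (0.0282 each), and with TMM and the preset one heat shock (0.730), plastid-encoded (0.577) and mitochondrion-encoded genes (0.135) did not. Heat shock genes were not lower in replicates 1 and 2 (0.2, upward), and plastid-encoded (0.707, upward) and mitochondrion-encoded genes (0.0650) did not pass in replicates 3 to 5. The heat shock median lay 2.25 above that of all genes and the mean 0.76 above, opposite to the test. Plastid transcription, clock, growth, reference and root genes, none called, also had signs that differed. The split was 18298 genes higher and 212 lower in replicates 1 and 2, 13161 and 478 in replicates 3 to 5, and 5890 and 5796 under TMM scaling of all.

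**Figure D3:**
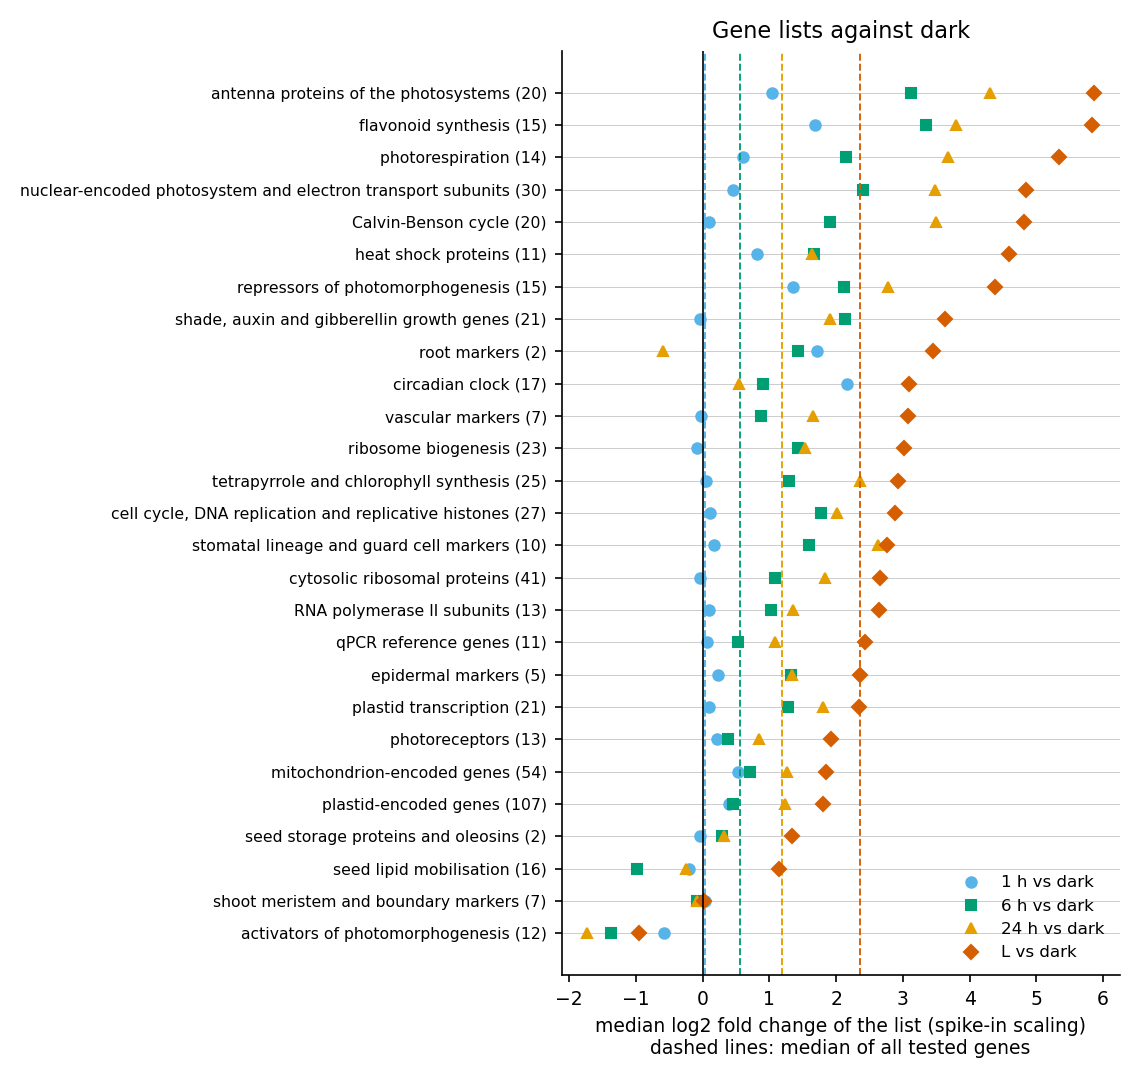
Median log2 fold change against dark (spike-in scaling) of 27 gene lists, with the number of genes tested in parentheses, 4 symbols for 1 h, 6 h, 24 h of light and L, and dashed lines for the median of all tested genes (0.03, 0.56, 1.19 and 2.35). Antenna genes reach 5.87 in L, and activators of photomorphogenesis lie at -0.95.

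**Figure D4:**
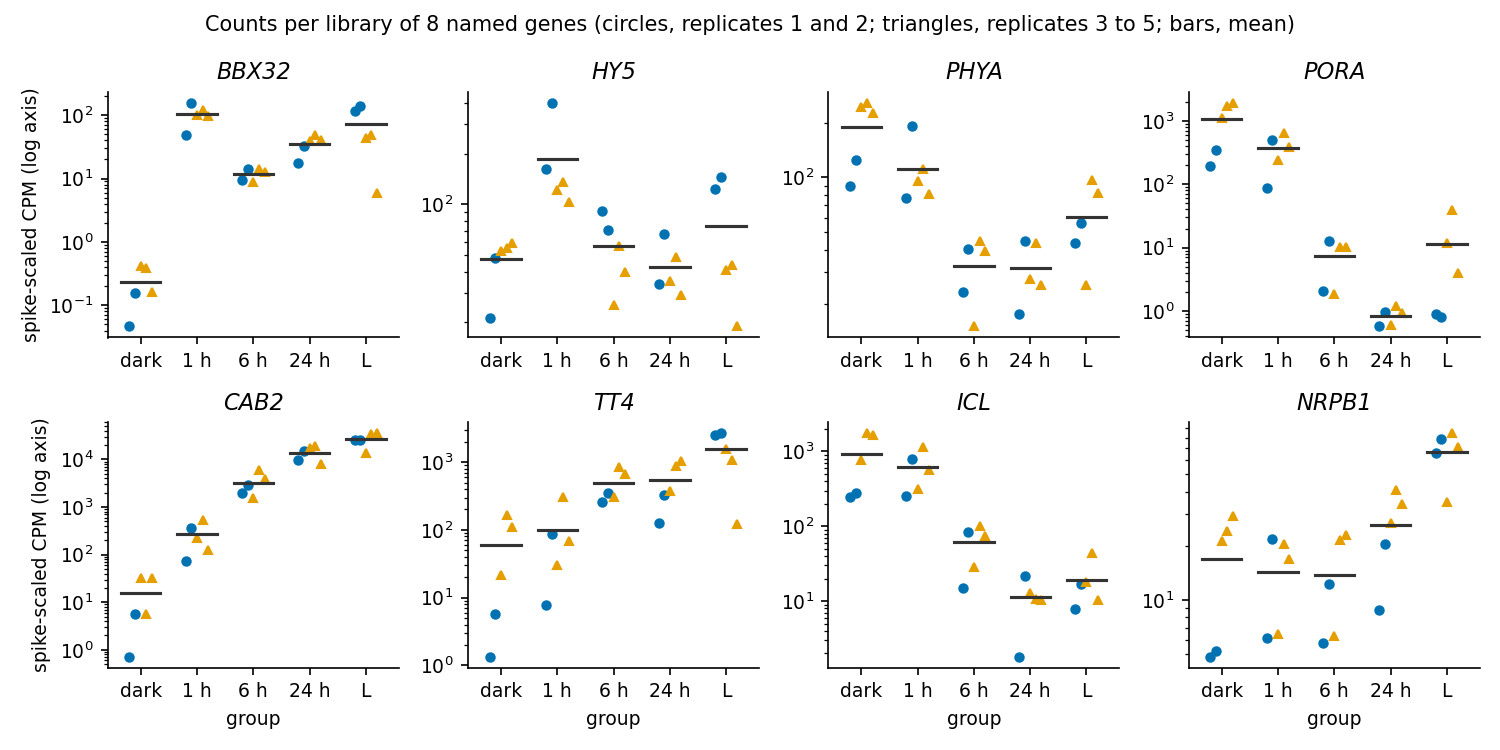
Spike-scaled CPM (log axis) of 8 genes in each library by group, with circles for replicates 1 and 2, triangles for replicates 3 to 5 and bars for the mean of 5 libraries. PORA has a mean of 1051 in dark and 0.851 at 24 h, and CAB2 goes from 15.3 in dark to 26820 in L.

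From 1 h to 6 h of light most photosynthesis and cell cycle genes rose, with some of the translation and growth genes, while a few clock and seed lipid genes fell. Of 20615 genes 2812 were higher and 643 lower, 5959 in all with the block against 3455 without it. AT3G10185 had no counts at 1 h and was at least 871-fold higher at 6 h, and the anthocyanin malonyltransferase gene AT5MAT (AT3G29590, 8.37 ± 0.91) and AT2G32550 (8.28 ± 0.87) followed. PORA (-5.64 ± 0.87), AT2G34020 (-5.24 ± 0.61) and AT3G18530 (-5.23 ± 0.55) fell most. Higher were 28 of 30 photosystem (30 adjusted over the list alone, TMM 29), 17 of 20 antenna (18, TMM 17), 14 of 20 Calvin-Benson (18, TMM 17) and 10 of 14 photorespiration genes (13, TMM 11). So were 15 of 27 cell cycle (23 adjusted over the list alone, TMM 22), 12 of 41 cytosolic ribosomal (22, TMM 26) and 10 of 23 ribosome biogenesis genes (19, TMM 17). Growth genes gave 10 higher and 1 lower (10 and 2 adjusted over the list alone, TMM 10 and 5), clock genes 1 and 5 (1 and 5, TMM 1 and 11) and seed lipid genes 4 lower (5, TMM 1 higher and 14 lower). Camera called 15 lists: photosystem (adjusted p = 6.51e-12), antenna (1.81e-08), Calvin-Benson (6.10e-08), cell cycle (9.58e-06), cytosolic ribosomal (2.48e-05), photorespiration (4.01e-05), ribosome biogenesis (7.11e-05), flavonoid (0.000216), growth (0.00743), stomatal (0.00837) and tetrapyrrole genes (0.0464) higher, and clock (3.78e-07), seed lipid (7.24e-07), activator (0.00743) and mitochondrion-encoded genes (0.0256) lower. An estimated correlation gave an adjusted p of 0.772 for tetrapyrrole, cytosolic ribosomal and mitochondrion-encoded genes and 0.716 for the other called lists. Within sets the tetrapyrrole list did not pass (0.0667 and 0.108), nor did mitochondrion-encoded genes in replicates 1 and 2 (0.770) or under TMM (0.444). Heat shock and reference genes, not called, had median, mean and test of differing sign. Replicates 1 and 2 gave 641 genes higher and 222 lower, replicates 3 to 5 2274 and 317, and TMM scaling 4379 and 4798 (47.7% higher against 81.4%). The total fell to 1876, 2024 and 2088 without 1 h replicates 1, 3 and 5 and to 1974 and 2222 without 6 h replicates 4 and 5.

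From 6 h to 24 h of light fewer genes were called, among them a few photosynthesis genes, all higher, and clock genes in both directions. Of 20615 genes 1405 were higher and 85 lower, 4033 in all with the block against 1490 without it. The ferric reductase gene FRO6 (AT5G49730, 6.38 ± 0.62), AT1G29720 (6.36 ± 0.60) and AT3G28270 (5.97 ± 0.75) rose most, and CP1 (-4.96 ± 0.71), ELF4 (-4.14 ± 0.67) and IGMT5 (AT1G76790, -3.77 ± 0.66) fell most. Clock genes gave 4 higher and 6 lower of 17, 7 and 7 adjusted over the list alone (TMM 4 and 7). Higher were 5 of 14 photorespiration (13 adjusted over the list alone, TMM 7), 4 of 20 Calvin-Benson (16, TMM 9), 2 of 20 antenna (13, TMM 6) and 1 of 30 photosystem genes (4, TMM 5). Lower were 2 of 11 heat shock (2 adjusted over the list alone, TMM 5), 2 of 21 growth (2, TMM 5) and 1 of 12 activator genes (3, TMM 5). Camera called 15 lists: photorespiration (adjusted p = 0.000997), Calvin-Benson (0.00179), antenna (0.00579) and photosystem genes (0.0157) higher, and heat shock (7.10e-07), activator (0.000167), meristem (0.000167), clock (0.00138), growth (0.00179), flavonoid (0.00193), root (0.00206), mitochondrion-encoded (0.0230), cell cycle (0.0449), ribosome biogenesis (0.0488) and plastid-encoded genes (0.0488) lower. Under an estimated correlation the adjusted p was 0.452 for heat shock, root and meristem genes, 0.608 for activators, 0.822 for flavonoid, clock, growth and photorespiration genes and 0.885 for the other called lists. Of the lists called lower, edgeR called no flavonoid, ribosome biogenesis, cell cycle, root or meristem gene. At an unadjusted p under 0.05 it had 1 flavonoid gene higher and 1 lower, 5 cell cycle genes higher, and 1 root and 2 meristem markers lower, and TMM called 2 flavonoid, 1 ribosome biogenesis and 3 meristem genes lower, and 2 cell cycle genes higher and 8 lower. With the block cell cycle (0.0686), plastid-encoded (0.896) and mitochondrion-encoded genes (0.0754) lost their calls, and under TMM these (0.0692, 0.862 and 0.793) and flavonoid (0.0891), clock (0.157) and root genes (0.186) did. The plastid-encoded median lay 0.26 above that of all genes, opposite to the test, and photoreceptor, cytosolic ribosomal, seed lipid, reference and vascular genes, not called, also had signs that differed. Replicates 1 and 2 gave 236 genes higher, 103 lower and 7 called lists, replicates 3 to 5 1210, 39 and 14, and TMM scaling 1966 genes higher and 1560 lower (55.8% higher against 94.3%). The total fell to 805, 959 and 658 without 6 h replicates 1, 2 and 3 and to 941 and 692 without 24 h replicates 2 and 4.

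With the spike-in L was higher than 24 h in many genes across most lists (median log2 fold change 1.18 over all genes). Of 20615 genes 10826 were higher and 106 lower. AT4G12510 (6.97 ± 1.18, on 6 counts at 24 h), the glutathione transferase gene GSTF2 (AT4G02520, 6.36 ± 1.18) and AT1G67865 (6.17 ± 0.79) rose most. AT5G15120 (-2.38 ± 0.51), ORS1 (AT2G41230, -2.22 ± 0.89, adjusted p = 0.0394) and PRN (AT3G59220, -1.53 ± 0.43) fell most. The ORS1 call was lost under TMM (0.0514) and without 24 h replicates 1, 2, 3 or 5 or L replicates 1, 3 or 4, with values from -2.40 to -1.87. Higher were 23 of 30 photosystem genes (27 adjusted over the list alone, TMM 0), 15 of 20 antenna (15, TMM 2), 13 of 20 Calvin-Benson (14, TMM 2) and 12 of 14 photorespiration genes (14, TMM 1). Plastid transcription gave 7 of 21, 5 adjusted over the list alone, though TMM called 2 higher and 8 lower. Of 7 meristem markers 1 fell, 1 adjusted over the list alone (TMM 1). Camera called 4 lists, all lower: plastid-encoded (adjusted p = 2.02e-14), mitochondrion-encoded (4.46e-10), meristem (1.32e-07) and plastid transcription genes (0.00754). These had an adjusted p of 0.369, 0.450, 0.338 and 0.906 with an estimated correlation. Within sets plastid transcription did not pass in replicates 1 and 2 (0.229), nor plastid-encoded genes in replicates 3 to 5 (0.140). Activator, flavonoid, clock, seed lipid and heat shock genes, none called, had median, mean and test of differing sign. Alone, replicates 1 and 2 gave 9334 genes higher and 140 lower, replicates 3 to 5 255 and 16, and TMM scaling 1232 and 959 (56.2% higher against 99.0%). The total fell to 3435 and 4865 without 24 h replicates 1 and 3 and to 5988 and 3802 without L replicates 1 and 2.

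Organelle-encoded reads per Drosophila read did not pass in any comparison when labels were exchanged over all libraries (exact permutation, lowest adjusted p over 20 tests 0.159), a test that takes in the difference between the sets of replicates. With labels exchanged only within the sets, plastid reads at 24 h and in L and mitochondrial reads in L were higher than in dark (exact permutation, adjusted p = 0.0417 each), and each of these rose in 5 of 5 replicate numbers. Mitochondrial reads at 6 h rose in 5 of 5 as well, without passing (0.1). Plastid reads differed from dark by a log2 value of 0.32 at 1 h (0.45 in replicates 1 and 2, 0.23 in replicates 3 to 5), 0.48 at 6 h (1.24 and -0.03), 1.15 at 24 h (1.35 and 1.03) and 1.54 in L (1.79 and 1.37). Mitochondrial reads differed by 0.42 (0.62 and 0.28), 0.64 (1.12 and 0.32), 0.47 (1.02 and 0.11) and 1.15 (1.55 and 0.88). As shares of Arabidopsis counts the directions turned after 1 h, with -0.43, -0.63 and -1.49 for plastids and -0.27, -1.31 and -1.88 for mitochondria at 6 h, at 24 h and in L. None of these shares passed over all libraries, and those at 24 h and in L passed within the sets (exact permutation, adjusted p = 0.0417 each). The plastid share is the measure that defined the sets, so its results within them carry the same limit. Against 24 h, L differed by 0.39 for plastid (0.45 and 0.35) and 0.68 for mitochondrial reads (0.53 and 0.77) per fly read, and by -0.87 and -0.58 as shares, of which the plastid share passed within the sets (0.0417).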

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

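For each named gene, in the groups of the comparisons that name it and in no others, each value was compared with the other 4 of its group by Dixon's ratio, which chance passes in about 5% of groups. Of 370 groups of named genes 17 held a value far from the others, and of 30 groups of library measures 0 did. In dark these were scpl10 in replicate 2 (0.0874 CPM, the others 0), AT2G32550 in replicate 5 (0.0977, the others 0), LDOX in replicate 5 (0.130, the others up to 0.0373), SQP1 in replicate 3 (0.0842, the others 0) and U1.8 in replicate 2 (36.7, the others 0.953 to 9.81). At 1 h they were PRR9 in replicate 2 (187, the others 45.9 to 78.1), HY5 in replicate 2 (399, the others 104 to 163) and TT4 in replicate 4 (308, the others 7.72 to 88.0). At 6 h they were FLP1 in replicate 2 (4.48, the others 0.294 to 0.858), AT3G18530 in replicate 2 (3.06, the others 0.572 to 1.22) and RNR2A in replicate 3 (11.5, the others 25.4 to 30.7). At 24 h they were DFR in replicate 5 (188, the others 6.49 to 46.6) and ATHSP22.0 in replicate 2 (3.47, the others 0.353 to 0.803). In L they were CYP96A5 and ATHSP22.0 in replicate 3 (0.294 each, the others 0), PORA in replicate 4 (39.6, the others 0.808 to 11.8) and ICL in replicate 4 (43.6, the others 7.95 to 18.1). Entries without a gene identifier held up to 0.741% of a library's counts.

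The tests of explanations in this part were chosen only after the results had been seen, except the ratio without the 50 nuclear genes with the most counts and the ratio with TMM-scaled Drosophila sizes, which had been planned as alternatives. The first pattern is the larger number of Arabidopsis reads per Drosophila read in L than in dark, a log2 difference of 3.08. Without the 50 nuclear genes with the most counts it was 2.85, which excludes a few abundant genes as the cause. With TMM-scaled Drosophila library sizes it was 2.86, which excludes a changed fly profile. More plant tissue per fly cell would shift all genes alike, and so would more RNA per cell or more cells per cotyledon. The median gene lay 2.37 higher under spike-in scaling than under TMM scaling, which cannot tell these apart, since tissue amounts were not recorded in the labels.

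The next pattern is that 1 h of light against dark has opposite directions within the 2 sets of replicates. One factor per library shared by all genes, such as the amount of fly RNA, could give it, since 348 genes differed between the sets at an unadjusted p under 0.05 under TMM scaling, where 5% of genes are 1031, but 12404 did under spike-in scaling. Ribosomal RNA genes are excluded, because the difference between the sets was -1.69 without them and -1.58 with them. Whether spread between libraries gave the difference cannot be told. Within pairs of like number the log2 differences were 0.42 and 1.56 in replicates 1 and 2 and -0.73, -0.25 and -0.78 in replicates 3 to 5, of 1 sign in each set, but exchanging the pairs between the sets gives an exact p of 0.1, the smallest that 10 assignments allow. Exchanging libraries without regard to pairs gave an exact permutation p of 0.0833 over 120 assignments. A response at another pace in some seedlings was not tested.

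The last pattern is the higher plastid share in replicates 3 to 5. Capture of RNA without a poly(A) tail would raise the mitochondrial share too, but that differed by -0.97, which excludes it as the only cause. Library size is excluded by total counts, which differed by -0.075. A single plastid gene is excluded as well, since without ATCG00790, which took 16.1% of plastid counts, the difference was still 1.76. No biological cause was tested, as every group holds libraries of both sets.

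Chance as the source of the calls was examined by drawing 24 splits of the 10 libraries of each comparison at random, the real one among them. For L against dark (17899 genes, highest other 640) and L against 24 h (10932, highest other 487) only the real split called that many. That is 1 of 24, the smallest share these draws can give, without adjustment over the 7 comparisons. The same held for 1 h against dark (835, highest other 11) and 24 h against dark (11152, highest other 9471). It also held for 24 h against 6 h (1490, highest other 10). These comparisons without L have like-numbered pairs, which the draws ignored, so chance is not excluded for them. Nor can chance be excluded in this way for 6 h against dark, where 5454 genes were called, 2 splits reached that number and the highest other called 6691. Nor can it for 6 h against 1 h, where 3455 genes were called, 3 splits reached that number and the highest other called 10307. The highest other split joined dark replicates 1 to 4 with 6 h replicate 3 in the former, and 1 h replicates 1, 3, 4 and 5 with 6 h replicate 3 in the latter. Each keeps 4 of the 5 libraries of a group together, which points to a structure of the samples in which 6 h replicate 3 stands apart from its group. In the 5 comparisons with like-numbered pairs, 16 splits, the real one among them, part every pair, too few for a share under 0.05. The real split called the most of these, and the highest other called 2 genes at 1 h, 2393 at 6 h and 30 at 24 h against dark, 0 for 6 h against 1 h and 9 for 24 h against 6 h.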

How the results depend on the processing

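Most results stood, but chiefly in refits without 1 library (2297 for named genes, 66 for lists). TMM moved 6 of 7 gene counts and an estimated correlation all 7 list results. Of 235 named-gene results, 216 were past the threshold. In all, 3173 such values kept side and direction, 38 reversed, 62 lost and 17 gained a call. For the ratio 97 stayed, 27 weakened, 4 strengthened and 5 reversed. Counts of called genes stayed within 1.5 times in 111 cases and moved in 43, list results in 93 and 26. Organelle values stayed in 135, gained a call in 3 and reversed in 12. Beyond the values given, the replicate block changed no call of a named gene or list in the paired comparisons. The tissue put in per fly cell is unknown, so the spike-in and TMM scalings differ by a factor that the data cannot settle. Of simulated 2-fold changes 4% were called, which need not hold where many genes change. An uncalled gene was not detectably changed at this depth rather than unchanged. The differences between the sets of replicates were tested for all 7 comparisons with edgeR. With the spike-in 0 genes differed after adjustment at 1 h (12404 unadjusted), 5 at 6 h, 1 at 24 h and 9190 in L against dark, 2 for 6 h against 1 h, 1 for 24 h against 6 h and 0 for L against 24 h. Under TMM at most 1 gene differed in any comparison, and 0 did at 1 h (348 unadjusted). For each value below the cause was not tested, except where fewer libraries or the bound of an exact test sets it.

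TMM over Arabidopsis genes called 2917 genes at 1 h, 10889 at 6 h and 11686 in L against dark, 9177 for 6 h against 1 h, 3526 for 24 h against 6 h and 2191 for L against 24 h. It called 9 lists for 24 h against 6 h and 9 for L against 24 h. Log2 values that reversed were RBCS1A at 1 h (0.074), HY5 (-0.37) and UBQ10 (-0.084) at 6 h, NRPB1 at 24 h (-0.50) and HY5 (-1.98) and NRPB1 (-0.24) in L. TMM over Drosophila genes called 7180 genes for L against 24 h. DESeq2 with Drosophila size factors called 1284 genes at 1 h and 5705 for 6 h against 1 h. DESeq2 with median-ratio size factors called 3440 at 1 h, 11262 at 6 h, 9623 for 6 h against 1 h, 4168 for 24 h against 6 h and 2894 for L against 24 h. A fit of only the groups compared called 3492 genes for 24 h against 6 h.

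With the replicate number as a block, edgeR called 715 genes higher and 331 lower at 1 h (median log2 -0.040, against 0.028 without it), 5814 and 1542 at 6 h and 12170 and 952 at 24 h against dark. It called 5959 genes for 6 h against 1 h and 4033 for 24 h against 6 h, and RBCS1A at 1 h was 0.029. The ratio was 1.81 at 24 h and 3.08 in L against dark, 0.88 for 24 h against 6 h and 1.28 for L against 24 h, none of which passed, as the exact sign-flip test over 32 assignments cannot go below 0.0625. For L the numbers do not mark pairs: 0 of 5 L libraries were closest to the dark library of their number and 3 to that at 24 h. There the block called 17819 genes higher and 450 lower against dark, and 14464 and 125 against 24 h. TMM with a block, added after the data were seen, called 3833 genes at 1 h, 12207 at 6 h, 10758 for 6 h against 1 h, 5152 for 24 h against 6 h and 3430 for L against 24 h.

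Replicates 1 and 2 alone, a choice made after the data were seen, gave 1803 genes at 1 h, 8709 at 6 h, 863 for 6 h against 1 h and 339 for 24 h against 6 h, and 7 lists for 24 h against 6 h. The ratio was 2.31 at 24 h and 4.19 in L against dark, 0.49 for 24 h against 6 h and 1.88 for L against 24 h, and no exact p can be below 0.333. Reversed at 1 h were PHYA (0.33), PORA (0.11), CAB1 (1.31), RBCS1A (1.33), ICL (0.99) and NRPB1 (1.47), at 6 h CCA1 (0.30) and NRPB1 (0.85), and at 24 h HY5 (0.53). Calls lost in this set were PIL1 (-1.51), FHY1 (-0.84), GATA2 (-1.24) and HB-2 (-1.81) at 1 h, MLS at 6 h (-0.48), ATHSP22.0 (-1.14), STM (-1.08) and KNAT2 (-0.40) at 24 h, PHYA (-1.10), PCK1 (-0.995), STM (-1.88) and CLV3, which had no counts in L, in L against dark and PRN in L against 24 h (-1.33). TT4 at 1 h (3.77), RBCS1A (2.2) and ACT2 (2.07) at 6 h and HY5 in L (1.95) gained a call. Replicates 3 to 5 alone gave 2877 genes at 6 h, 6472 at 24 h and 271 for L against 24 h, where 8 lists were called. The ratio was -0.59 at 1 h, 1.48 at 24 h and 2.35 in L against dark, 1.14 for 24 h against 6 h and 0.87 for L against 24 h, and no exact p can be below 0.1. Reversed were plastid reads at 6 h (-0.027), ACT2 at 1 h (-0.52), and HY5 at 6 h (-0.46) and in L (-0.69). Calls were lost here for HY5 (1.11), HSFA2 (2.03) and HSP70 (2.2) at 1 h, PHYB (1.14), AT5G03850 (1.28) and RPS6 (1.62) at 6 h, KNAT2 at 24 h (-1.95) and AT5G15120 (-1.72), ORS1 (-2.29) and PRN (-1.71) in L against 24 h.

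With labels exchanged only within the sets of replicates, a test added after the data were seen, the ratio of L against 24 h lost its call (1.28), and plastid reads at 24 h (1.15) and in L (1.54) and mitochondrial reads in L against dark (1.15) gained one. The sets were defined by the plastid share, so the calls gained by plastid reads are no independent support.

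For 24 h against 6 h the ratio lost its call with TMM-scaled Drosophila sizes (0.67), without the 50 nuclear genes with the most counts (0.78) and without the 50 such Drosophila genes (0.81). As shares of Arabidopsis counts, plastid reads reversed to -0.43 at 6 h, -0.63 at 24 h and -1.49 in L against dark and -0.87 in L against 24 h. Mitochondrial shares reversed to -0.27, -1.31, -1.88 and -0.58. Camera with an estimated correlation called 0 lists in all 7 comparisons. With TMM, added after the data were seen, it called 2 each at 1 h, 24 h and in L and 0 elsewhere. Fry, which tests whether a list moves 1 way and not against other genes, called 1 list at 1 h, 22 in L, 0 for 24 h against 6 h and 13 for L against 24 h.

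Leaving out 1 library at a time, the ratio ranged from -0.21 to 0.21 for 1 h and from 0.68 to 1.18 for 6 h against dark, from 0.73 to 1.14 for 6 h against 1 h, from 0.63 to 1.05 for 24 h against 6 h and from 1.11 to 1.49 for L against 24 h. At 1 h against dark 378 to 690 genes were higher, 130 to 269 lower and the median ranged from -0.28 to 0.25. Without 1 h replicate 2 there were 378 higher and 269 lower, without dark replicate 2 405 and 232. Called genes ranged from 1876 to 5042 for 6 h against 1 h, from 658 to 2041 for 24 h against 6 h and from 3435 to 13650 for L against 24 h. Called lists ranged from 4 to 9 for L against 24 h. Plastid reads ranged from -0.23 to 0.84 at 1 h and from -0.062 to 0.80 at 6 h. Gene values with both signs were ACT2 (-0.23 to 0.26), CAB1 (-0.61 to 0.22), NRPB1 (-0.47 to 0.055), RBCS1A (-0.27 to 0.20) and TT4 (-0.32 to 1.53) at 1 h and CCA1 (-0.46 to 0.19) at 6 h. For 23 of 235 values of named genes the rarer group keeps 3 counts or fewer with 1 library left out, and no range is given for them. Of the other 212 values most ranged over more than 1.5-fold, and 19 over more than 1 in log2. Besides TT4 at 1 h, the 19 all kept sign and call. At 1 h they were ELIP1 (4.05 to 5.54), F3H (2.997 to 4.29) and AT5G42760 (7.73 to 8.80), and at 6 h bbx23 (-10.42 to -8.81), FLP1 (-8.14 to -6.62), ELIP1 (6.68 to 8.01), LDOX (8.89 to 10.11) and TT4 (2.70 to 3.81). At 24 h ATHSP22.0 (-3.65 to -2.24), ELIP1 (5.6 to 6.93), TT4 (2.82 to 3.97) and MLS (-4.38 to -3.31) did so. In L these were PORA (-7.88 to -6.21), ELIP1 (6.18 to 7.54), 4CL3 (6.46 to 7.61) and TT4 (4.39 to 5.51). Between other groups they were AT2G32550 (7.83 to 8.98) and AT3G18530 (-5.79 to -4.78) for 6 h against 1 h.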

Other observations

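By class of transcript, described here without a test between classes, the median log2 fold change of L against dark was 2.38 for 18688 protein-coding genes, of which 16225 were higher and 349 lower. It was 1.70 for 423 long non-coding RNAs (231 higher, 18 lower), 2.28 for 65 small nucleolar RNAs (27 and 4), 1.86 for 27 small nuclear RNAs (10 and 1) and 1.04 for 28 microRNA genes (12 and 3). At 24 h the microRNA genes had a median of -0.26, with 4 higher and 9 lower.

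Replicates 3 to 5 held a lower share of small nucleolar and small nuclear RNA counts than replicates 1 and 2, by a log2 difference of -1.51, and of ribosomal RNA counts, by -1.94 (stratified permutation p = 1e-05 each, the smallest it can give). The ratio of nuclear to Drosophila counts differed by 0.13 between these sets on average (permutation p = 0.598), but in both directions, by 1.28 in dark, -0.30 at 1 h, -0.20 at 6 h, 0.45 at 24 h and -0.56 in L.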
